A study of Mus musculus with 2 samples.

How the data were processed

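H3K4me3 ChIP-seq peaks of 2 biological replicates of mouse embryonic stomach at 16.5 days were read from 4 peak lists: 1 for each replicate, 1 for the pooled replicates and 1 of replicated peaks. The lists are on the mouse build mm10, per the labels. The aligner, the peak caller, their versions and the filters are not given in the sources used here. Per the deposited notes beside the lists, each replicate's list was derived from that replicate's alignments and further files of unstated content, which were not the same set for both replicates, the pooled list from the alignments of both, and the replicated list from the other 3 lists. All 26799 rows of the replicated list are rows of the pooled list, and 24852 of them (92.7%) overlap a peak of both replicates by at least 50% of the smaller peak. A replicated peak is therefore not always a peak in both replicates' own lists: 1899 did not overlap a peak of both by even 1 bp. The labels name a possible control experiment, which was not analysed here.

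Each peak has a score, which the authors deposited and which was not used further. The signal value of each peak was deposited by the authors, and how it was normalized is not given in the sources used here. The −log10 p-value and −log10 q-value of each peak were deposited by the authors as well. The lists were not cut at a strict threshold, since the smallest −log10 p-value is 2.03 in the replicated list and 42 of its peaks have a q-value above 0.05. Signal, p and q are the authors' own values of each peak, and they were used to describe, rank or filter peaks within a list. The number of reads per sample is unknown, so no interval for counting error can be given, and differences in depth between the replicates could move the number of weak peaks and the width of domains. The 2 replicates limit every SD.

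Peak positions were set against the GENCODE M21 annotation of the same build. The start sites were the 54361 distinct 5′ ends of coding transcripts of 21853 protein-coding genes on chromosomes 1 to 19, X and Y. A gene was called marked when a peak of the replicated list overlapped a window of 1000 bp on each side of any of its start sites. Peaks with gaps of at most 1000 bp were joined into 22505 domains, and the breadth of a gene is the width of the widest domain that overlaps one of its windows. Peaks were called shared when they overlapped by at least 50% of the smaller peak. Chance was described by shuffling peaks within chromosomes 100 times. The CpG observed/expected ratio was computed from the reference sequence over each window, the highest ratio among its start sites was taken for a gene, and a gene was called CpG-rich at 0.6 or more.

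The labels give 1 group, so no groups were compared. The tests, fixed before the data were examined, used 24 lists of genes written from textbook knowledge (328 different genes, all found in the annotation), the Hox genes and the olfactory and vomeronasal receptors. The lists cover housekeeping, pan-epithelial, endodermal, gastric secretory, forestomach, mesenchymal, smooth muscle, interstitial, neural, enteroendocrine, endothelial, mesothelial, leukocyte and erythroid genes, signalling pathways, and markers of intestine, pancreas, liver, lung, skeletal muscle, heart muscle, forebrain and germline. The share of marked members was tested against all other coding genes by Fisher's exact test, two-sided. The median breadth of marked members was tested against random draws of as many marked genes by a permutation test with 100000 resamples, two-sided, for the 24 lists with at least 3 marked members. The share of members in the broadest 5% of domains was tested by Fisher's exact test for the same 24 lists. The p-values were adjusted by the Benjamini-Hochberg method and a list was called at an adjusted p under 0.05. Genes are the units of these tests. Their p-values say whether a list stands apart from other genes in this tissue, and genes that share a domain or a list are not independent.

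The genes to be named were also fixed before the data were examined. They are the coding genes at the 10 broadest domains, a fixed number of marked and unmarked members of the 6 lists of stomach layers (the marked ones with the broadest domains), the marked member with the broadest domain of every other list, the few marked or unmarked members where a list has at most 3, the genes nearest the 5 peaks with the highest signal at any place and away from start sites, and the Hox genes as a class. Other names were chosen after their values were seen, and this is said beside them.

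The alternatives fixed beforehand were the pooled list, each replicate alone, peaks with a −log10 q-value of at least 5, windows of 500 and 2500 bp, the 5′ end of the gene record as the only start site, CpG-rich genes alone, no merging and gaps of 3000 bp, the broadest 10%, and other rules for shared peaks. Draws matched on the CpG ratio (permutation tests with 100000 draws, in 20 bins for marking and 10 for breadth) and replicated peaks that overlap both replicates were added after the data had been seen. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The interval functions were tested on simulated data, 2000 intervals per set, against bedtools 2.31.1, and all 9 quantities were equal. In 100 simulations over the 21853 genes, the marking test called 0% of lists of 16 members that did not differ and 100% of those with every member marked or with 1 of 4 marked. In 100 simulations over the 14774 marked genes, the breadth test called 0.4% of lists of 11 members that did not differ and 94.4% of those whose breadth was doubled. Lists of other sizes were not simulated, so these rates do not describe the smaller lists.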

Results

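H3K4me3, a methylation mark on histone H3 that sits mainly at transcription start sites, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of mouse embryos of strain B6NCrl at 16.5 days of development. The series held 1 group of 2 biological replicates, each a pool of stomachs from embryos of both sexes. Replicate 2 came from 41 embryos, and the number for replicate 1 was not given. The labels named no second tissue, age or treatment. The tests below therefore set gene lists against other genes within this tissue, and they do not compare samples or conditions. The number of reads behind each peak list is unknown, because the lists hold no counts.

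H3K4me3 covered a similar part of the genome in both replicates. The list of replicate 1 held 31932 peaks and that of replicate 2 held 31242 (mean 31587 ± 488, SD, n = 2), and the peaks covered 36.7 ± 1.04 Mb (SD, n = 2). The authors' pooled list held 33195 peaks. Their replicated list, which was used for all results at genes, held 26799 peaks with a median width of 1208 bp and covered 38.8 Mb. Of the peaks of replicate 1, 81.3% overlapped a peak of replicate 2 by at least 50% of the smaller peak, and 86.6% of the peaks of replicate 2 overlapped a peak of replicate 1. Shuffled peaks of replicate 1 gave a mean of 1.99%. The Jaccard index of the covered base pairs was 0.835, against a mean of 0.00752 after shuffling. Across 24905 matched pairs of peaks, Spearman's rho was 0.956 for the authors' signal value and 0.957 for the width. These correlations are across peaks, which are not independent replicates.

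Peaks without any overlap in the other replicate were narrow and weak. They numbered 5194 in replicate 1 and 3413 in replicate 2, with median widths of 224 bp and 218 bp, against 1128 bp and 1032 bp for the other peaks of the same lists. Of these peaks, 18.3% in replicate 1 and 18.4% in replicate 2 lay at a coding start site, against 60.4% and 60.0% of the others. In both lists 0% of them had a signal value above the median of their list.

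Most of the mark lay at start sites of protein-coding genes. Of 26788 replicated peaks on the assembled chromosomes, 15923 (59.4%) overlapped a window of 1000 bp on each side of a coding start site, against a mean of 4.24% after shuffling, and these peaks held 79.9% of the covered base pairs. In the replicates' own lists the share was 54.5 ± 1.35% (SD, n = 2). In all, 14774 of 21853 coding genes (67.6%) were marked, meaning that a replicated peak overlapped the window of at least 1 of their start sites. The replicates' own lists marked 14834 ± 38.2 genes (SD, n = 2), of which 14697 were marked in both. Of 8223 genes with a CpG-rich start-site window, 99.1% were marked, against 48.6% of the 13630 other genes.

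Genes of the cell layers of the developing stomach were marked almost throughout, while genes for the products of the mature gastric glands mostly were not. All members were marked in the lists of foregut and gastric endoderm regulators (15 of 15), gastric mesenchyme (19 of 19), smooth muscle (14 of 14), endothelium (14 of 14), pan-epithelial genes (16 of 16), hedgehog signalling (14 of 14), Wnt, BMP and FGF signalling (19 of 19) and housekeeping genes (12 of 12). Of the enteric neuron and glia genes 17 of 18 were marked, the exception being Plp1, a myelin protein gene. Of the Hox genes 36 of 39 were marked. These 10 lists stood above the other coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 26 lists, adjusted p from 0.00292 for the Hox genes to 0.0226 for housekeeping genes and for enteric neurons and glia). Against draws of coding genes matched on CpG content, chosen after the data had been seen, gastric mesenchyme, smooth muscle and endothelium stood above and the other 7 lists did not pass the permutation test (adjusted p from 0.145 to 1). For 6 of these 7, all but enteric neurons and glia, the central 95% of the draws reached the full list, so this test could not have placed them above, and the 36 marked Hox genes lay below their mean draw of 36.6. Of the gastric secretory products 6 of 18 were marked, below the 67.6% of other genes (Fisher's exact test, adjusted p = 0.0121), with 6 marked in replicate 1 and 4 in replicate 2. The call was lost and the direction turned against the matched draws (4.74 in the mean draw, permutation test, adjusted p = 1), while 16.7% were marked by the replicated peaks that overlap both replicates (Fisher's exact test, adjusted p = 0.000192), a setting also chosen after the data had been seen. The gastric mucin genes Muc5ac and Muc6 were unmarked, and so were Atp4a and Atp4b, the subunits of the acid-secreting proton pump, which were picked from the list after their values were seen. Its marked members with the broadest domains were Cldn18, a tight-junction gene, with 9004 bp (9137.5 ± 199 bp in the replicates, SD, n = 2), and Bhlha15, a regulator of secretory cells, with 3106 bp (2674 ± 983 bp, SD, n = 2). Neither gene encodes a secreted product, so the list is wider than its name. The marked Tff1 and Pgc, chosen after their values were seen, had domains of only 291 bp and 231 bp. Pgc had no domain in the list of replicate 2.

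Genes of some other organs and cell types were marked less often. By the same Fisher's exact test, 4 of these lists lay below other genes. They were, with the adjusted p of that exact test, liver with 2 of 14 marked (adjusted p = 0.000515), skeletal muscle with 4 of 12 (adjusted p = 0.0428), germline with 1 of 12 (adjusted p = 0.00045) and the olfactory and vomeronasal receptors with 5 of 1463. The marked liver genes were Ttr, with a domain of 1563 bp, and Apoa1, with 1258 bp (1751.5 ± 708 bp in the replicates, SD, n = 2), and the marked germline gene was Dazl, an RNA-binding protein gene of germ cells, with 788 bp. The Apoa1 domain (chromosome 9, 46229691 to 46230948) lay downstream of the gene start at 46228580 and outside its window. That domain ran past the gene end at 46230466. Apoa1 was therefore marked only at the start site of another of its transcripts. Of the liver genes 21.4% were marked with the list of replicate 2 alone, the pooled list or windows of 2500 bp, and 7.14% with windows of 500 bp or gene records' 5′ ends (Fisher's exact test, adjusted p from 6.82e-05 to 0.00342). With windows of 2500 bp 16.7% of the germline genes (Fisher's exact test, adjusted p = 0.00258) and 0.547% of the receptors were marked. Against the matched draws the liver and skeletal muscle calls were lost (permutation test, adjusted p = 1 and 0.269). Of all coding genes other than the receptors 72.4% were marked, and Vmn1r4 had the broadest domain among the receptors, 2692 bp. Most of that domain (chromosome 6, 56922213 to 56924904) lay upstream of the gene start at 56924015. Whether the domain belongs to this gene or to a neighbour was not tested. The forestomach squamous epithelium list had 14 of 16 members marked, all but Krt6a and Ivl, and did not pass Fisher's exact test (adjusted p = 0.137). With windows of 500 bp 75% of its members were marked (Fisher's exact test, adjusted p = 0.627). Some of its marks therefore lay over 500 bp from a start site. The forebrain list had 11 of 12 marked, all but Neurod6. That list and those of mesothelium (8 of 8), interstitial cells of Cajal (6 of 6), enteroendocrine cells (11 of 17), leukocytes (9 of 15), heart muscle (7 of 12), erythroid cells (4 of 11), intestine (6 of 14), pancreas (6 of 14) and lung (4 of 10) did not pass it either (Fisher's exact test, adjusted p from 0.0756 to 0.799). Mesothelium and interstitial cells of Cajal had every member marked and still reached only p = 0.0605 and 0.187 before adjustment (Fisher's exact test). The test could therefore not have placed lists of their size above other genes.

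Several calls changed with the CpG content of the genes used for comparison. Among CpG-rich genes alone, 99.1% were marked, so lists of these sizes could not be called above the others even with every member marked. There 0 of 24 lists stood above the others, at either an adjusted or an unadjusted p under 0.05, and the germline list stood below (Fisher's exact test, 25% marked, adjusted p = 5.89e-05). Against the matched draws, 6 lists stood above (permutation test, two-sided, adjusted p from 0.000347 to 0.0298). These were forestomach squamous epithelium (14 of 16 marked, 7.4 in the mean draw), smooth muscle (14 of 14, 8.69 in the mean draw), mesothelium (8 of 8, 4.94), leukocytes (9 of 15, 4.00), gastric mesenchyme (19 of 19, 16.04) and endothelium (14 of 14, 10.6). The germline list (1 of 12, 7.95 in the mean draw) and the receptors (5 of 1463, 129.8) stood below. The coding genes include these 1463 receptors, whose median CpG ratio was 0.141. Receptors among the draws would lower the mean draw of lists with a low CpG ratio. Leukocytes, above the matched draws, were called below other genes at a −log10 q-value of at least 5 (Fisher's exact test, 33.3%, adjusted p = 0.0217) and with gene records' 5′ ends (33.3%, adjusted p = 0.0293). Intestine (Fisher's exact test, 35.7%, adjusted p = 0.0323) and lung (30.0%, adjusted p = 0.0321) were also called below others at that q-value. Lung was called with windows of 500 bp too (Fisher's exact test, 30.0%, adjusted p = 0.0319). With the peaks that overlap both replicates, lung (Fisher's exact test, 30.0%, adjusted p = 0.031) and pancreas (35.7%, adjusted p = 0.0315) were called. With the list of replicate 1 alone, the skeletal muscle call was lost and lung was called below others (Fisher's exact test, 41.7%, adjusted p = 0.092, and 30.0%, adjusted p = 0.0287), and with that of replicate 2 alone pancreas was called below others (Fisher's exact test, 35.7%, adjusted p = 0.0314). The skeletal muscle call was also lost with the pooled list, windows of 2500 bp and gene records' 5′ ends (Fisher's exact test, 41.7% each, adjusted p from 0.091 to 0.153). The endothelium call was lost at a −log10 q-value of at least 5 (Fisher's exact test, 92.9%, adjusted p = 0.0653) and with gene records' 5′ ends (85.7%, adjusted p = 0.18).

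**Figure D1:**
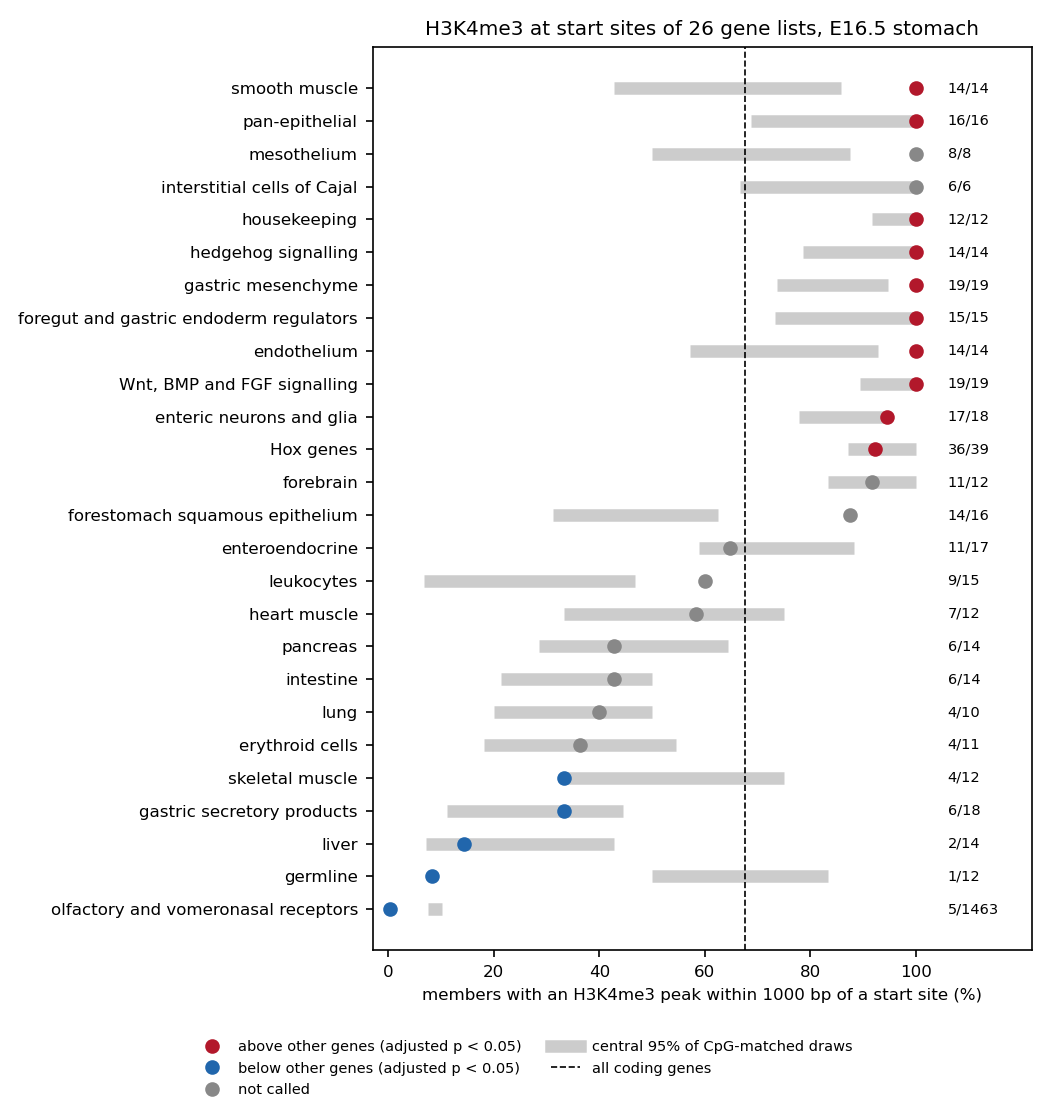
Share of the members of each of 26 gene lists with a replicated H3K4me3 peak within 1000 bp of a start site (x axis, percent; points), with the number marked and the number of members at the right. Grey bars give the central 95% of draws matched on CpG content, the dashed line is the share of all coding genes (67.6%), and colours show the Fisher's exact test; smooth muscle lies at 14 of 14, gastric secretory products at 6 of 18 and germline genes at 1 of 12.

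Domains, in which peaks with gaps of at most 1000 bp were joined, were broad at genes of the stomach's mesenchyme and at regulators of its endoderm. The median breadth over all marked coding genes was 2155 bp. In the gastric mesenchyme list it was 8666 bp (8833.5 ± 204 bp in the replicates' own lists, SD, n = 2), with Ptch1, the hedgehog receptor, at 19835 bp (20680 ± 1257 bp, SD, n = 2) and Hoxa5 at 14729 bp (16065.5 ± 1887 bp, SD, n = 2). In the list of foregut and gastric endoderm regulators it was 5870 bp (6462.5 ± 910 bp, SD, n = 2), with the pioneer factor gene Foxa1 at 17349 bp (16957.5 ± 1025 bp, SD, n = 2) and Gata6, a zinc-finger factor of endoderm, at 12054 bp (11721 ± 444 bp, SD, n = 2). The median was 4890 bp in Wnt, BMP and FGF signalling (4513 ± 693 bp, SD, n = 2), with the receptor gene Fgfr2 at 8668 bp, and 4654 bp in hedgehog signalling (4680.5 ± 165 bp, SD, n = 2). In smooth muscle it was 4567 bp (4554 ± 162 bp, SD, n = 2), with Tpm2, a tropomyosin, at 6319 bp (6262.5 ± 38.9 bp, SD, n = 2) and Myl9, a myosin light chain, at 6272 bp (5927 ± 22.6 bp, SD, n = 2). It was 4086.5 bp in Hox genes (2883.75 ± 27.9 bp, SD, n = 2), 3933 bp in pan-epithelial genes (3740.75 ± 24.4 bp, SD, n = 2), with Klf5 at 9840 bp, and 3613 bp in housekeeping genes (3626.25 ± 34.3 bp, SD, n = 2), with Actb at 6173 bp. In the forestomach list it was 3343 bp (3381.75 ± 363 bp, SD, n = 2), with the homeobox gene Pitx1 at 13531 bp (13458.5 ± 65.8 bp, SD, n = 2) and Grhl3, an epidermal regulator, at 5437 bp (4881.5 ± 315 bp, SD, n = 2). These 9 lists were broader than random draws of as many marked genes (permutation test, two-sided, 100000 resamples, Benjamini-Hochberg over 24 lists, adjusted p from 6.86e-05 to 0.00556). The smallest p these resamples can give is 2e-05 before adjustment. With peaks left unmerged, the forestomach median was 1750 bp, below the 2012 bp of all marked genes, the gastric mesenchyme median was 5104 bp and the Hox median 2080 bp, and the calls of the forestomach and Hox lists were lost (permutation test, adjusted p = 0.417 and 0.848). With gaps of 3000 bp the Hox median was 8368 bp.

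By the same permutation test 5 lists were narrower (adjusted p from 0.00162 to 0.0141). Their medians were 1270 bp for leukocytes, with Coro1a, an actin-binding protein gene, at 2430 bp (2688.5 ± 991 bp in the replicates, SD, n = 2), 1236 bp for enteroendocrine genes (1018.25 ± 172 bp in the replicates, SD, n = 2), 918.5 bp for skeletal muscle (846.5 ± 91.2 bp, SD, n = 2), with Mylpf at 3578 bp, 885 bp for heart muscle (832.25 ± 32.2 bp, SD, n = 2), with Nkx2-5 at 4675 bp but 5575 bp in replicate 1 and 2489 bp in replicate 2, and 613 bp for the receptors. Most of the Mylpf domain (chromosome 7, 127206264 to 127209841) lay upstream of the gene start at 127208890. Whether that domain belongs to Mylpf or to a neighbour was not tested. The leukocyte median was 1196 bp with the list of replicate 1 and 286 bp with that of replicate 2, and the receptor median 548 bp and 272.5 bp, with 375 bp in the pooled list. The leukocyte call was lost against draws matched on the CpG ratio and at a −log10 q-value of at least 5 (permutation test, adjusted p = 0.889 and 0.189). With gaps of 3000 bp the enteroendocrine median was 3054 bp, above that of all marked genes, and the enteroendocrine and heart muscle calls were lost (permutation test, adjusted p = 0.139 and 0.547). In the enteroendocrine list Isl1, a homeobox gene of islet and motor neuron development, had the broadest domain, 12708 bp (12805.5 ± 149 bp, SD, n = 2). Enteric neurons and glia had a median of 2748 bp, with Hand2 at 11800 bp (12128.5 ± 670 bp, SD, n = 2) and Phox2b, a regulator of autonomic neurons, at 7059 bp (6263 ± 918 bp, SD, n = 2), and endothelium had one of 2917 bp, with Egfl7 at 6000 bp. Neither list passed the permutation test (adjusted p = 0.104 and 0.0586). Endothelium was called broader with the list of replicate 1 alone (permutation test, 3059 bp, adjusted p = 0.0211), of replicate 2 alone (2952 bp, adjusted p = 0.0244). It was also called with the pooled list (permutation test, 3196.5 bp, adjusted p = 0.0216) and against matched draws (adjusted p = 0.0074). Enteric neurons and glia were called broader with the pooled list (permutation test, 3463 bp, adjusted p = 0.00304). Without merging their median, 1840 bp, lay below that of all marked genes. Gastric secretory products had a median of 1457.5 bp and did not pass (permutation test, adjusted p = 0.104). They were called narrower with the list of replicate 1 alone (permutation test, 728 bp, adjusted p = 0.0016), the pooled list (1025 bp, adjusted p = 0.0064) and unmerged peaks (801 bp, adjusted p = 0.0024). The forebrain list, with 2471 bp, was called broader with gaps of 3000 bp (permutation test, 4434 bp, adjusted p = 0.00501). Among the other lists that did not pass the test, the members with the broadest domains in the replicated list were Wt1 of mesothelium (6292 bp, but 3569.5 ± 302 bp in the replicates' own lists, SD, n = 2), Kit of interstitial cells of Cajal (4595 bp), Tal1 of erythroid cells (4599 bp), Cdx2 of intestine (4283 bp), Nkx6-1 of pancreas (4647 bp, but 7545 bp in replicate 1), Nkx2-1 of lung (3076 bp, but 1811 bp in replicate 1) and Dlx1 of forebrain (7825 bp). In single replicates other members, chosen after their values were seen, were broader, namely Foxj1 of lung (2257 bp) and Etv1 of interstitial cells of Cajal (6047 bp) in replicate 1, and Podxl of mesothelium (4296 bp) in replicate 2.

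**Figure D2:**
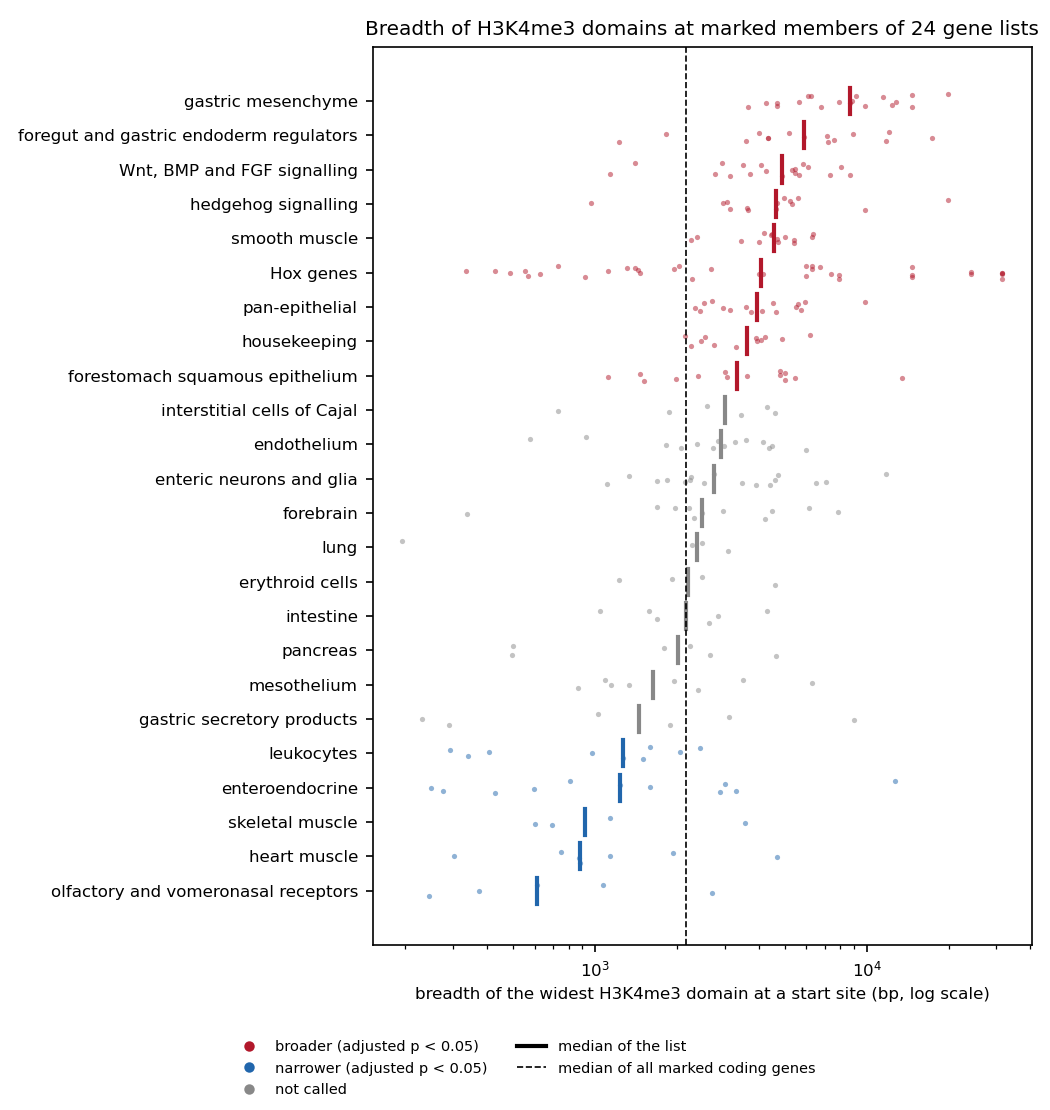
Breadth of the widest H3K4me3 domain at the start sites of each marked member (x axis, bp, log scale; points) of 24 gene lists, with the median of each list as a vertical bar and the median of all marked coding genes (2155 bp) as a dashed line. Colours show the permutation test on the median; the gastric mesenchyme list has the highest median, 8666 bp, and the receptor list the lowest, 613 bp.

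The broadest 5% of the domains that held a coding start site were wider than 4731 bp and held 801 marked genes. Of the gastric mesenchyme genes 15 of 19 lay in them, against 5.33% of other marked genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 24 lists, adjusted p = 6.88e-15). The other lists above the rest were the Hox genes (17 of 36), foregut and gastric endoderm regulators (9 of 15), Wnt, BMP and FGF signalling (10 of 19), hedgehog signalling (6 of 14), forestomach squamous epithelium (6 of 14), smooth muscle (5 of 14) and pan-epithelial genes (5 of 16), by Fisher's exact test with adjusted p from 9.98e-12 to 0.00367. Some genes stand in more than 1 list, such as Ptch1 in mesenchyme and hedgehog signalling, Bmp4 in mesenchyme and BMP signalling and Hoxa5 in mesenchyme and the Hox genes, so these tests are not independent. Neighbouring Hox genes share domains, so the Hox test counts some domains more than once and its p-value overstates the evidence. The forestomach call was lost with the list of replicate 1 alone (Fisher's exact test, 21.4%, adjusted p = 0.0816), without merging (21.4%, adjusted p = 0.0846) and with gaps of 3000 bp (14.3%, adjusted p = 0.428), and enteric neurons and glia were called with the list of replicate 2 alone (23.5%, adjusted p = 0.0293). With that list 57.1% of the marked smooth muscle genes lay in the broadest domains (Fisher's exact test, adjusted p = 8.17e-07). Enteric neurons and glia were also called with the pooled list (Fisher's exact test, 35.3%, adjusted p = 0.000576) and in the broadest 10% (41.2%, adjusted p = 0.00313). By the same exact test, forebrain was called with gaps of 3000 bp (36.4%, adjusted p = 0.0151) and housekeeping genes in the broadest 10% (50%, adjusted p = 0.00234). The Hox share was 27.8% without merging (Fisher's exact test, adjusted p = 4.15e-05). With gaps of 3000 bp the calls of smooth muscle (Fisher's exact test, 21.4%, adjusted p = 0.133) and pan-epithelial genes (6.25%, adjusted p = 1) were also lost.

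The 10 broadest domains measured from 14513 bp to 31441 bp. The widest held start sites of Hoxb3, Hoxb4, Hoxb5 and Hoxb6 on chromosome 11 (96298168 to 96329608, mm10), with that of Hoxb4 nearest its centre. In replicate 1 the widest domain at Hoxb4 measured 12074 bp and in replicate 2 it measured 31436 bp. The domain at Nr2f2, a nuclear receptor gene, covered the whole gene with 25266 bp on chromosome 7 (70345886 to 70371151) and measured 25238.5 ± 10.6 bp in the replicates (SD, n = 2). A domain of 24141 bp on chromosome 6 (52157376 to 52181516; 24373.5 ± 689 bp in the replicates, SD, n = 2) covered Hoxa2 and held a start site of Hoxa1. The domain of Ptch1 on chromosome 13 (63554195 to 63574029) lay within the gene for 97.8% of its length. Meis2, a homeobox gene, had 17981 bp (17889 ± 99.0 bp, SD, n = 2), and the domain of Foxa1 on chromosome 12 (57534845 to 57552193) covered the whole gene. The T-box gene Tbx2 had 15883 bp (15829 ± 233 bp, SD, n = 2), and a domain of 14729 bp was shared by Hoxa3, Hoxa5 and Hoxa6. Meis1 had 14698 bp (14995 ± 567 bp, SD, n = 2) and the zinc-finger gene Zfp503 14513 bp (12677 ± 2656 bp, SD, n = 2).

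Within the Hox clusters the median breadth was higher in groups 1 to 8 than in groups 9 to 13. All 23 genes of groups 1 to 8 were marked, with a median breadth of 7412 bp, and the median in the replicates' own lists was 6738 ± 945 bp (SD, n = 2). Of the 16 genes of groups 9 to 13, 13 were marked, with a median of 919 bp and 676 ± 11.3 bp in the replicates (SD, n = 2). Hoxc11, Hoxc12 and Hoxd12 were unmarked. Single genes, chosen after their values were seen, lay on the other side of the 2155 bp of all marked genes. These were Hoxb1 (628 bp, 830 ± 522 bp in the replicates, SD, n = 2), Hoxd1 (1401 bp) and Hoxc8 (2034 bp, 1587.5 ± 479 bp, SD, n = 2) of groups 1 to 8, and Hoxa9 of groups 9 to 13. Hoxa9 shared a domain of 6270 bp with Hoxa7 in the replicated list, but in replicate 1 its widest domain measured 2094 bp and that of Hoxa7 3239 bp. The median breadth in groups 1 to 8 was 19426.5 bp in the Hoxb cluster, 14729 bp in Hoxa, 7329 bp in Hoxc and 2476.5 bp in Hoxd. The order of Hoxa and Hoxb turned in replicate 1, with 17400 bp and 9740 bp, and the Hoxc median was 3189 bp in replicate 2. Neighbouring Hox genes share domains, so no test was made between these classes. The medians of the classes differed by more than the spread between the replicates, which does not measure the spread among genes. Single marked genes ranged from 628 to 31441 bp in groups 1 to 8 and from 336 to 6270 bp in groups 9 to 13, so the classes overlapped.

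**Figure D3:**
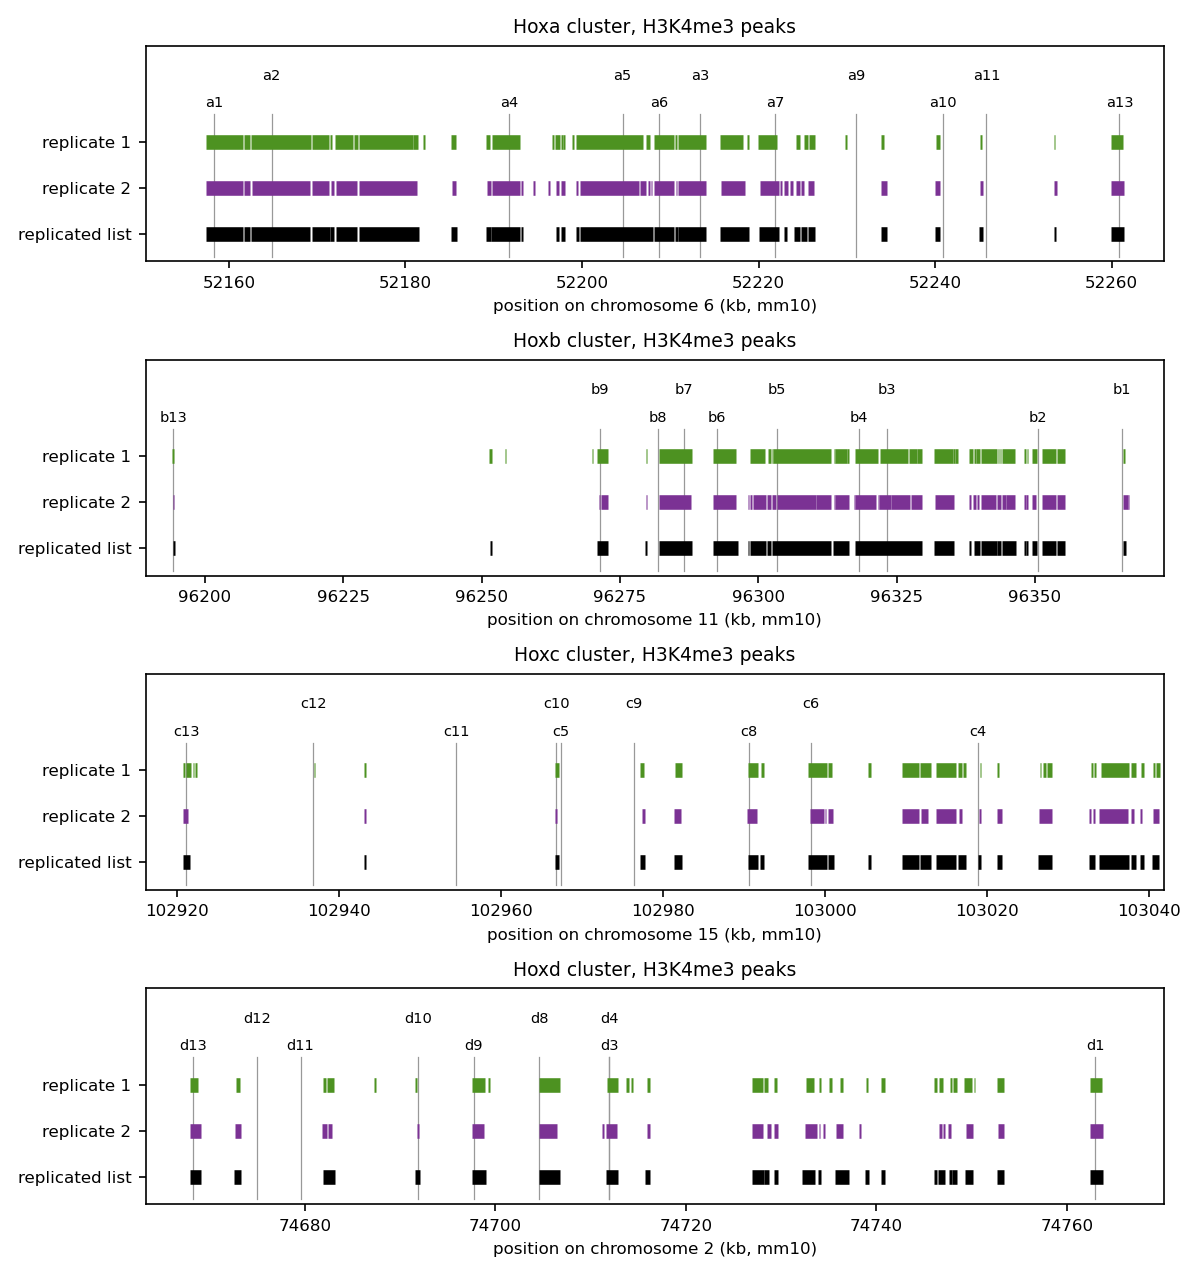
H3K4me3 peaks of replicate 1, replicate 2 and the replicated list (horizontal bars) along the 4 Hox clusters (x axis, position in kb on mm10), with grey lines at the 5′ end of each gene record; start sites of shorter or longer transcripts are not drawn. Wide blocks lie at groups 1 to 8 of the Hoxa and Hoxb clusters, including the 31441 bp domain with start sites of Hoxb3, Hoxb4, Hoxb5 and Hoxb6.

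The highest signal value, 80.8, was that of a peak of 1577 bp at Psmb2, a proteasome subunit gene, on chromosome 4 (126677016 to 126678592). It was followed by Smndc1, a splicing factor gene (79.9), Cltc, the clathrin heavy chain gene (77.7), Med19, a Mediator subunit gene (77.7), and A730071L15Rik (77.5), whose peak summit lies in an intron of Nudcd3.

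Peaks away from start sites were weaker. In all, 8632 replicated peaks (32.2%) lay farther than 1000 bp from the start site of any annotated gene. Their summits fell in exons for 982 peaks, in introns for 3870 and between genes for 3780. Exons held 11.4% of these summits, against 3.28% after shuffling. Their median signal value was 5.18, against 36.2 for the peaks at start sites, and their median width 526 bp against 1706 bp. The 5 with the highest signal were a peak in an intron of Nup160 (69.7, chromosome 2, 90678518 to 90680481), one between genes with Fcgr4 as the nearest coding gene at 19368 bp (67.1), one at 6010 bp from Zfp869 (62.9), one in an intron of Prdm2 (61.1) and one in an exon of Sf3b5 (60.3). All but the Nup160 peak lay within 1000 bp of a transcript start in the RefSeq annotation.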

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

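The replicated list held 11 peaks on scaffolds outside the assembled chromosomes, which no result at genes used. They were looked at because any signal there lies outside the main measurement, and the genes named here were chosen after their values were seen. The peak with the highest signal value (46.0) spans 15481 to 17543 of a scaffold assigned to chromosome 4, within 1000 bp of a coding gene record with a clone-based name. On a scaffold assigned to the X chromosome, peaks lay at Vamp7, a vesicle fusion gene (41.0), and at Tmlhe, an enzyme of carnitine synthesis (23.5). No explanation for these peaks was tested.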

How the results depend on the processing

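The draws matched on CpG and the replicated peaks that overlap both replicates were settings chosen after the data had been seen, and the others were planned. The number of marked genes (14774), the 9 lists with broader domains and the 8 lists in the broadest domains stayed within 1.5 times their values in every setting run for them. The peaks found in 1 replicate numbered 5978 and 4177 in replicates 1 and 2, against 5194 and 3413, when those overlapping by under 50% of the smaller peak were added, the only other setting run for them. The lists above other genes numbered 10, against 0 among CpG-rich genes and 6 against matched draws, of which 3 were among the 10. For 6 of the 7 that lost the call there, the matched draws reached the full list, so that test could not keep them. Those below numbered 5, against 8 at a −log10 q-value of at least 5, 1 among CpG-rich genes and 2 against matched draws. The 5 lists with narrower domains became 3 with gaps of 3000 bp. The share of peaks at coding start sites (59.4%) was 51.2% in the pooled list, 62.9% at the stricter q-value, 56.97% and 66.9% with windows of 500 and 2500 bp, 50.8% with gene records' 5′ ends, and 53.6% to 55.5% leaving out each replicate. The shared peaks of replicates 1 and 2 were 73.3% and 74.9% with reciprocal overlap, 94.4% and 98.3% among peaks above the median signal of each list, and 93.7% and 92.5% at the stricter q-value. Peaks away from start sites rose from 8632 to 13263 in the pooled list. Among single lists, 67 values changed direction, 11 of them with a call in either setting and 56 with a call in neither. For marking, they lay among CpG-rich genes in gastric secretory products, erythroid, heart muscle and receptors (100% each, of 1 CpG-rich gene), skeletal muscle (100% of 2), intestine, pancreas and lung (100% each, of 3), enteroendocrine (100% of 4) and Hox genes (91.7% of 24), so most rest on very few genes. Against matched draws they lay in gastric secretory products (33.3%), leukocytes (60.0%), erythroid (36.4%), intestine (42.9%), lung (40.0%), heart muscle (58.3%), forebrain (91.7%) and Hox genes (92.3%). Enteroendocrine genes changed direction with the pooled list and without replicate 2 (70.6% each) and with gene records' 5′ ends (64.7%), and leukocytes with the pooled list and without replicate 1 (73.3% each). For breadth without merging, they were forestomach (1750 bp), enteric neurons and glia (1840 bp), intestine (1789 bp), pancreas (2014 bp), lung (1541.5 bp) and forebrain (1974 bp). With gaps of 3000 bp they were enteroendocrine (3054 bp), erythroid (2194.5 bp), intestine (2162.5 bp) and pancreas (3749.5 bp), and against matched draws gastric secretory products (1457.5 bp), leukocytes (1270 bp) and forebrain (2471 bp). The intestine median also changed side with the pooled list (2162.5 bp), the stricter q-value (1691 bp) and without replicate 1 (1710.5 bp, against 2267.5 bp without replicate 2), and that of pancreas with the pooled list (2313 bp) and without replicate 1 (2264 bp, against 2034 bp without replicate 2). For the broadest domains with gaps of 3000 bp, they were pan-epithelial (6.25%), interstitial cells of Cajal, intestine and pancreas (16.7% each), erythroid (25%) and heart muscle (14.3%). Without merging they were interstitial cells of Cajal and pancreas (16.7% each), and gastric secretory products and mesothelium (0% each). In the broadest 10% they were interstitial cells of Cajal (33.3%), enteroendocrine (9.09%), erythroid (25%), intestine and pancreas (16.7% each) and heart muscle (14.3%). At the stricter q-value they were mesothelium (0%), pancreas (16.7%) and heart muscle (14.3%), and with the pooled list interstitial cells of Cajal (16.7%). Without replicate 2 they were interstitial cells of Cajal (33.3%), mesothelium (0%), erythroid (25%), pancreas (14.3%) and heart muscle (12.5%), and without replicate 1 mesothelium (0%). Of the other values of single lists, 201 for marking, 138 for breadth and 133 for the broadest domains kept their direction and side of the threshold, while 23, 3 and 4 lost a call and 11, 9 and 5 gained one. CpG-rich genes are nearly all marked (99.1%), so no list of these sizes could be called above them. The cause of the other changes was not tested. Depth is unknown and limits what can be said of weak peaks.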

Other observations

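The tests of transcription factors and products of other organs were chosen after the marking had been seen, the draws matched on CpG content were added after the data had been seen, and the Hox and forestomach lists were picked for a separate test because they lost their call with unmerged peaks.

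The genes in this paragraph and the next were chosen after their values were seen. On the Y chromosome 4 of 183 coding genes were marked, namely Ddx3y, Eif2s3y, Kdm5d and Uty. On the X chromosome 52.4% of 948 coding genes were marked. The non-coding RNA gene Xist, which acts in X inactivation, had a domain of 3493 bp in these pools of both sexes. The imprinted non-coding genes H19, Meg3 and Kcnq1ot1 had domains of 3180 bp, 3146 bp and 4460 bp.

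Of 7434 long non-coding RNA genes whose start sites lie over 5000 bp from any coding start site, 782 (10.5%) were marked, with a median breadth of 1075 bp. Among all long non-coding RNA genes, Carmn, known from smooth muscle, had a domain of 11864 bp on chromosome 18 (61654663 to 61666526), and the nuclear RNA genes Neat1 and Malat1 had 9350 bp and 8613 bp. The domain of 8892 bp at Sox2ot was also that of Sox2, which lies within it. Among the 803 peaks away from start sites with a signal above the median of the replicated list, 229 (28.5%) lay within 1000 bp of a transcript start of the RefSeq annotation, against 9.71% of the 7829 weaker ones and a mean of 2.04% after shuffling. Of the stronger ones 5.48% lay inside a domain that also held a coding start site, against 22.6% of the weaker ones.

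The design has 1 group, so no biological explanation was tested for the patterns that follow. In the lists of intestine, pancreas, liver, lung, skeletal muscle, heart muscle, forebrain and germline, 25 of 29 transcription factor genes were marked, against 16 of 71 other genes, called products here. Not every list holds both kinds of gene. In the 5 organs that do, 14 of 17 factors and 13 of 45 products were marked. CpG content may account for the factors, since the central 95% of draws matched on it gave 23 to 28 marked of 29. Of the products outside the germline list, with a median CpG ratio of 0.214, 15 of 59 were marked against 11 to 22. The draws could include the receptors (5 of 1463 marked, median ratio 0.141), which would lower that range. For these products the draws therefore do not decide. CpG content cannot account for the germline list, 1 of 12 marked against 6 to 10, and what sets these genes lower stays open. Cells of other organs in the dissected tissue cannot be told apart from CpG content, because the 13 marked of 45 products in the 5 organs with both kinds of gene lay within the 9 to 18 of matched draws. Receptors among the draws could have lowered that range too.

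The peaks found in 1 replicate may be weak peaks near the listing threshold, since 0% of them in either replicate had a signal above the median of their list. This shows that they were weak, but not how near the threshold they lay. Their median −log10 p-value by the authors was 4.57 in replicate 1 and 4.79 in replicate 2. The highest were 18.3 and 21.2, and the smallest of the whole lists 2.01 and 2.05. Replicate 1 held 1.52 times as many peaks found in 1 replicate as replicate 2. The replicates' lists were derived from different sets of further files, and this cannot be told apart from a difference between the replicates themselves, because each set goes with 1 replicate.

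The lists with broader domains could owe their breadth to CpG content at the start sites, but all 9 stayed broader than draws of marked genes matched on it. The matched ratio covers only the window of 1000 bp on each side of a start site. How far CpG-rich sequence extends beyond the windows was not matched, so its part in the breadth stays open. The 9 lists could also owe their breadth to peaks of neighbouring genes merged into 1 domain, but 7 of the 9 stayed broader with unmerged peaks. For the forestomach list, which lost its call, 0% of the marked members had a domain that joined a peak at another coding gene, which argues against neighbouring genes and leaves the joining of each gene's own peaks open. For the Hox genes the share was 36.1%, against 0.684% of all marked genes, between the bounds set beforehand, so merging cannot be told apart from broad marking of each gene. The abundance of each cell type in the tissue was not measured and stays open.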
